A study of Micropterus salmoides with 45 samples.

How the data were processed

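Liver of largemouth bass (Micropterus salmoides), a freshwater fish, was sequenced in 45 libraries from 15 groups of 3, which crossed 3 levels of dissolved oxygen with 5 sampling times. Per the labels' protocols, fish of 6 months at 20 °C were spread over 9 tanks of 30 fish, 3 tanks per oxygen level, and were fasted throughout. Oxygen was lowered with nitrogen gas, and the moment at which it had reached its level was taken as 0 h. Total RNA was made into libraries with a TruSeq kit, sequenced as 125-bp paired-end reads and assembled de novo with Trinity, per the labels' protocols. The labels do not state whether the 3 libraries of a group came from separate tanks or separate fish, so the p-values measure the spread between these samples. Each oxygen level had tanks of its own and the tank of each library is not known. A difference between tanks and a difference between oxygen levels could therefore not be separated here.

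The deposited values, 1 table per library, were read as RPKM, which is reads scaled by gene length and by the total reads of the library. The file headers give identifiers and library titles and name no unit, so the unit was taken from the values themselves. The aligner, the counter and the rule by which genes were listed are not given in the sources used here. The tables listed 2660 assembled genes from 2245 Trinity components. The table of control 8 h replicate 2 as used here ended after 2527 genes, and the other 133 values of that library were treated as missing. The identifiers are those of the assembly, the files do not pair them with names, and none of them matched the reference gene table at hand. Lists of genes of glucose and lipid metabolism, of the hypoxia response and of other cell types, fixed before the data were examined, therefore could not be applied, and genes are given by identifier.

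Depth was recovered from the RPKM values, which are reads divided by gene length and library total. A single set of whole gene lengths and whole library totals turned all 117443 values above 0 into whole read numbers, within a tolerance of 0.01 and with a largest distance of 6.23e-05. The recovered totals ran from 29986862 to 33433838 reads, and the gene lengths from 204 to 29856 bp with a median of 2584 bp. The listed genes held 10.9% to 15.0% of the reads of a library, with a median of 422 reads per gene and library. Low even read numbers exceeded low odd ones (338 values of 2 reads against 157 of 1 and 173 of 3), so both mates of a pair were mostly counted. In simulated tables the same procedure returned all 45 totals and 1468 of 1499 gene lengths exactly.

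The tests ran on log2(RPKM + 1), a scale that understates the fold change of low genes. Genes with at least 1 RPKM in at least 3 libraries were kept, which left 2656. One model with the 15 group means was fitted to all 45 libraries with limma 3.58.1 in R 4.3.3, using moderated variances with an intensity trend. A gene is called when its Benjamini-Hochberg adjusted p is under 0.05. The contrasts were severe hypoxia against control, moderate hypoxia against control and severe against moderate hypoxia at each time, and each as the mean of the differences at 4, 8, 12 and 24 h (12 libraries against 12). The 12 libraries of a level came from at most 3 tanks, and dependence between times within a tank was not modelled. F-tests asked for any difference among the 5 control times, and for a difference in the response to hypoxia among 4, 8, 12 and 24 h. The design foresaw a count test for the case of counts and this test for normalized values, and the second applied. Genes are named by a rule fixed in advance for features without names: per contrast, the 2 largest rises and the 2 largest falls among called genes with a mean of at least 5 RPKM, and for the mean contrasts with the same sign at all 4 times. The same-sign condition was applied to the single times as well. A largest or leading rise or fall is therefore the largest among such genes, and others may have changed more. Where 6 or fewer genes were called, the named ones outside this rule were chosen after their values were seen.

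Each library was also given a severe-response score: the mean log2(RPKM + 1) of the genes called higher minus that of the genes called lower in the mean contrast of severe hypoxia, refitted without the time scored, and set relative to the mean of the control libraries of that time. Scores were compared by 2-sided exact permutation tests. With 3 libraries against 3 the smallest p these can give is 0.1. Fold changes of both hypoxia levels against the same controls share the chance values of those controls, so they were set beside simulated unchanged groups, beside the covariance difference and beside fits with the control libraries divided between the levels.

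Pairwise comparisons of the recovered reads found no duplicated library: the lowest chi-square per gene over 990 pairs was 28.2. On simulated libraries with known changes and 2505 genes tested, the mean contrast of severe hypoxia recovered 34% of genes changed 1.5-fold, 68% at 2-fold, 94% at 4-fold and 96% at 8-fold, with 3 false calls of 149. At 4 h it recovered 2%, 26%, 84% and 80%, with 4 false calls of 100. Simulated unchanged groups gave at most 3 calls in each of 27 comparisons. The genes were simulated independently of each other, so this does not give the rate of false calls where a library shifts many genes together.

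The alternatives planned in advance were limma without the trend, quantile normalization, a pseudocount of 0.1, no filter, the replicate number as a block, a 2-fold minimum, a model of only the groups compared, the mean without each time, and each library left out in turn. For the correlation of the 2 hypoxia levels, the division of the control libraries between them was planned as well. Chosen after seeing the data were limma with voom weights on the recovered reads, the mean contrasts without 3 libraries that stood apart from their groups, and the tests between neighbouring times.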

Results

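The study asked how acute hypoxia changes the use of glucose and lipid in the liver of largemouth bass. Control fish were held at 7 mg/L dissolved oxygen, the moderate group at 3.0 ± 0.2 mg/L and the severe group at 1.2 ± 0.2 mg/L. Liver was taken at 0, 4, 8, 12 and 24 h, with 3 libraries for each oxygen level and time and 45 in all. The tables covered 2660 genes, whose mean levels had a median of 5.55 RPKM and reached 3516 RPKM. Library totals ran from 29986862 to 33433838 reads, so depth differed little between groups. The listed genes were already rich in differences: 93.1% had a mean at least 2-fold away from control at some time in a hypoxia group, and each reached 2.0 RPKM or more in some library. The shares of called genes below describe this list, not all genes of the liver.

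Severe hypoxia changed most of the listed genes. Over the mean of 4 to 24 h, 1229 of 2656 genes were higher and 1058 lower than in control (limma). The largest rise was that of c84833_g1, by 5.92 on the log2 scale (SE 0.45, adjusted p = 4.8e-13). Its mean in the control groups was at most 0.329 RPKM, against 69.6 ± 45.8 RPKM (SD, n = 3) at 4 h, 329 ± 360 at 8 h, 125 ± 119 at 12 h and 120 ± 162 at 24 h of severe hypoxia. The gene c88960_g1 rose by 4.66 (SE 0.21, adjusted p = 1.4e-19) with far less spread, from 0.74 to 1.65 RPKM in the control groups to 26.3 ± 10.5 at 4 h and 90.1 ± 24.0 at 24 h (n = 3). For both genes, all 12 severe libraries at 4 to 24 h lay above all 12 control libraries. The largest falls were those of c84317_g3 (log2 change -3.24, SE 0.57, adjusted p = 7.31e-06) and c84881_g1 (log2 change -3.23, SE 0.59, adjusted p = 1.07e-05). At 24 h, c84317_g3 stood at 13.4 ± 2.83 RPKM in control and 0.73 ± 0.733 in severe hypoxia (n = 3). Its control libraries differed widely at earlier times, with 43.4, 3.44 and 138 RPKM in the 3 libraries at 4 h. Across the control libraries c84881_g1 varied together with it (r = 1 after rounding, in deviations from the group means). The 2 falls are therefore not independent of each other. With a 2-fold minimum, 668 genes were called.

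**Figure D1:**
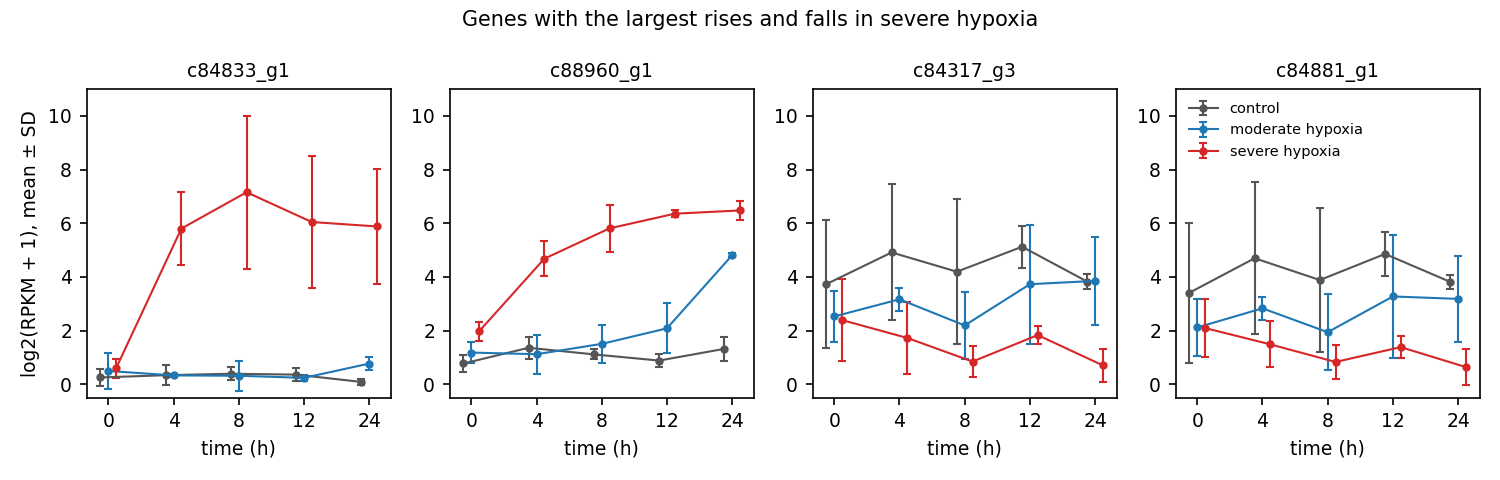
Levels of the genes with the largest rises and falls in severe hypoxia, as log2(RPKM + 1) against time in hours (categories, not to scale), with points for the mean and bars for the SD of 3 libraries. The gene c88960_g1 rose from 4 h in severe hypoxia and at 24 h in moderate hypoxia, where it reached 27.1 ± 1.47 RPKM. At 24 h c84833_g1 stood at 0.727 ± 0.288 RPKM in moderate hypoxia and 0.0679 ± 0.0789 in control. On the log2(RPKM + 1) scale, which understates changes of low genes, this was 0.68 and not called (limma, adjusted p = 0.567).

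The number of called genes in severe hypoxia grew from 4 to 12 h. At 0 h, when the oxygen had just reached its level, limma called no gene (0 also without the trend and with voom, and 161 genes at an unadjusted p under 0.05). There were 176 higher and 78 lower genes at 4 h, 570 and 495 at 8 h, 977 and 889 at 12 h, and 1082 and 689 at 24 h. Of the genes called higher at any of these times, 176 were first called at 4 h, 430 at 8 h, 507 at 12 h and 215 at 24 h, and 99 were called at all 4 times. For lower genes these numbers were 78, 435, 458 and 129, with 35 called at all 4 times. The abundant gene c89999_g1 was among the largest falls at 4 h (log2 change -1.86, SE 0.42, adjusted p = 0.00479), from 582 ± 79.6 to 176 ± 84.3 RPKM (n = 3), while c84833_g1 had risen by 5.46 (SE 0.91, adjusted p = 0.000189) and c73830_g1 by 4.09 (SE 0.85, adjusted p = 0.00238). At 12 h the largest rise was that of c84828_g3, by 6.09 (SE 0.66, adjusted p = 2.03e-08), from 0.521 ± 0.0364 to 106 ± 31.7 RPKM, and the largest fall that of c90004_g1 (log2 change -3.61, SE 0.69, adjusted p = 7.76e-05). At 24 h c84828_g3 stood at 117 ± 57.5 RPKM against 1.74 ± 1.88 in control, and c90721_g1 had fallen by 3.17 (SE 0.45, adjusted p = 1.23e-06). A set of 23 listed genes had reads in all 3 severe 8 h libraries and in at most 4 of the 39 libraries outside control 8 h and severe 8 h. It was picked after the data were seen but without use of the control 8 h libraries, and all 23 genes were among those called higher at 8 h. None of them had reads in control 8 h replicates 1 and 2 and all had reads in control 8 h replicate 3, with a summed level of 36.6 RPKM against 49.1 to 68.9 in the severe 8 h libraries. The count at 4 h was 138 without severe 4 h replicate 3, and 3 in a model of the 6 compared libraries alone. In that model c84833_g1 (adjusted p = 0.0569), c73830_g1 (adjusted p = 0.144) and c89999_g1 (adjusted p = 0.229) were not among the called genes. Without severe 4 h replicate 3, the change of c89999_g1 at 4 h was -1.36 and no longer called (adjusted p = 0.0641). Scaling decided which direction was more frequent at 8 and 12 h and in the mean of 4 to 24 h. After quantile normalization the calls were 158 higher and 154 lower at 4 h, 537 and 606 at 8 h, 879 and 917 at 12 h, and 889 and 853 at 24 h, where the median change of all genes went from 0.22 to 0.03. In that mean they were 1111 and 1115, and the median change went from 0.17 to 0.03.

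**Figure D2:**
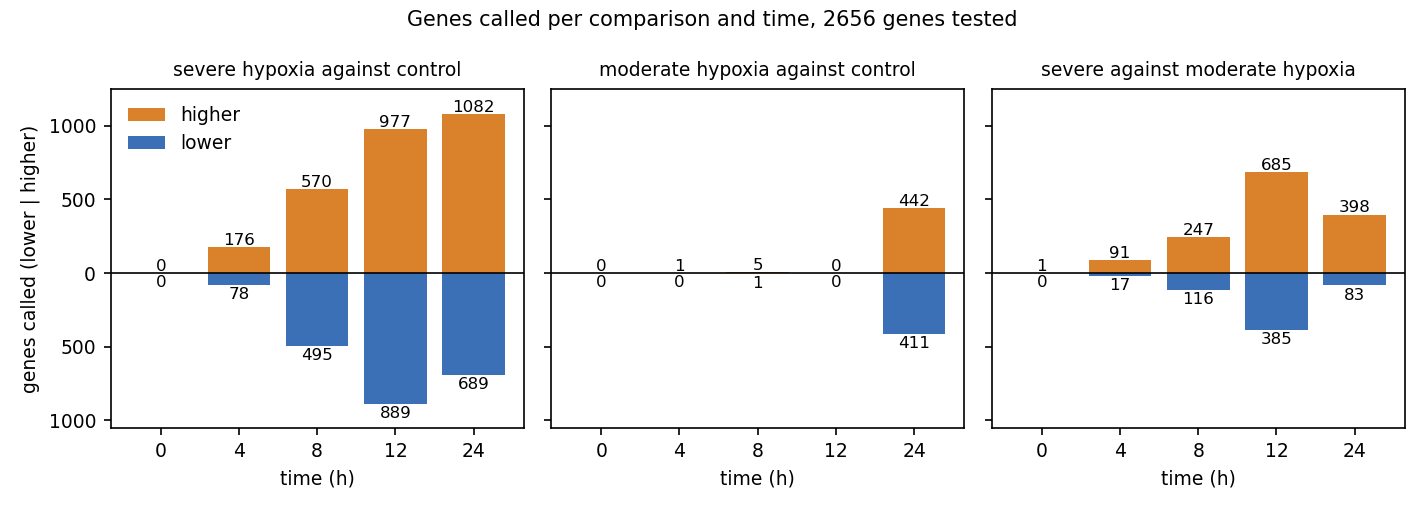
Numbers of genes called higher (above 0) and lower (below 0) at each time in hours, for severe hypoxia against control, moderate hypoxia against control and severe against moderate hypoxia, out of 2656 tested. Severe hypoxia had 254 called genes at 4 h and 1866 at 12 h, and moderate hypoxia 6 at 8 h and 853 at 24 h.

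The size of the severe response differed among 4, 8, 12 and 24 h for 644 genes (F-test in limma), with 1085 at an unadjusted p under 0.05. Between neighbouring times, tests chosen after seeing the data called 11 genes for 8 h against 4 h, 15 for 12 h against 8 h and 5 for 24 h against 12 h. For c88960_g1 the response grew by 1.37 on the log2 scale (SE 0.58, adjusted p = 0.366) from 4 to 8 h, so this step did not pass the test. Without severe 4 h replicate 1 the count over time was 423, and in a model of the compared groups alone it was 321.

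Most calls in moderate hypoxia fell at 24 h, when 442 genes were higher and 411 lower than in control (limma). The gene c84828_g3 had risen by 4.33 on the log2 scale (SE 0.66, adjusted p = 3.9e-05), from 1.74 ± 1.88 to 46.6 ± 8.09 RPKM (n = 3), and c84828_g4 of the same assembly component by 3.76 (SE 0.53, adjusted p = 1.25e-05). The falls were led by c84023_g1 (log2 change -2.64, SE 0.45, adjusted p = 0.000136) and c89999_g1 (log2 change -2.28, SE 0.42, adjusted p = 0.000312), the second from 584 ± 185 to 120 ± 41.8 RPKM (n = 3). Genes of 1 component can be parts or copies of 1 gene, and reads can be divided between them. The count at 24 h was 426 without control 24 h replicate 1, 563 without control 24 h replicate 3 and 547 without moderate 24 h replicate 2. With a 2-fold minimum it was 560. After quantile normalization 449 genes were higher and 455 lower.

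Over the mean of 4 to 24 h, 506 genes were higher and 484 lower in moderate hypoxia than in control. The largest rises were those of c86982_g16 (log2 change 1.82, SE 0.37, adjusted p = 0.000702) and c84828_g3 (1.73, SE 0.33, adjusted p = 0.000392). The gene c86982_g16 stood at 45.9 ± 4.13 RPKM at 24 h against 6.19 ± 5.53 in control (n = 3), and all 3 moderate libraries lay above all 3 controls at that time. They also did at 8 h, narrowly (lowest moderate 21.2, highest control 20.4 RPKM). At 4 h its mean was 25.2 ± 18.9 RPKM in moderate hypoxia and 29.7 ± 42.6 in control, where replicate 3 stood at 78.9. At 12 h moderate replicate 2 (9.24 RPKM) lay below control replicate 1 (13.1). The largest falls were those of c88665_g1 (-1.40, SE 0.41, adjusted p = 0.00965) and c84881_g1 (-1.51, SE 0.59, adjusted p = 0.0423). The falls were no longer called after control 4 h replicate 3, control 8 h replicate 3 and moderate 12 h replicate 2 were left out together, a check chosen after seeing the data, with changes of -0.69 and -0.81. The call of c84881_g1 also ended without control replicate 1 or 3 of any of the 4 times, or moderate 4 h replicate 1 or 3, 8 h replicate 3, 12 h replicate 1 or 2, or 24 h replicate 1 or 2, with changes of -1.51 to -1.20. It ended as well with a pseudocount of 0.1 (adjusted p = 0.0674), with voom (adjusted p = 0.0633), in a model of the compared groups (adjusted p = 0.0834) and in the mean without any 1 of the 4 times (adjusted p from 0.091 to 0.119). The mean rested largely on 24 h: without it 190 genes were called, without 12 h 627, and with a 2-fold minimum 46. The change of c84828_g3 was 0.87 without 24 h and that of c88665_g1 -1.31 without 24 h, and neither was called.

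Before 24 h, moderate hypoxia gave few calls. Only c90755_g4 was called at 4 h, higher in moderate hypoxia at 4.70 ± 2.33 RPKM than in control at 0.391 ± 0.399 (n = 3, log2 change 2.0, adjusted p = 0.00705). At 8 h, 5 genes were higher, among them c91374_g1 (1.35, SE 0.30, adjusted p = 0.0389) and c91501_g6 (1.09, SE 0.24, adjusted p = 0.0389), and c90605_g2 was lower (-1.49, SE 0.30, adjusted p = 0.0199). At 0 h and at 12 h limma called no gene, and neither did limma without the trend or with voom, with 90 and 452 genes at an unadjusted p under 0.05. These counts turned on single libraries: at 12 h, 98 genes were called higher and 202 lower without moderate 12 h replicate 2. At 4 h the count was 66 without control 4 h replicate 2, 3 without control 4 h replicate 1 and 0 without moderate 4 h replicate 2. At 0 h it was 2 without moderate 0 h replicate 1 and 6 without replicate 2. At 8 h it was 11 without moderate 8 h replicate 3, 0 without moderate replicate 1 or 2 or control replicate 2, 1 without control replicate 1, when none of the 3 genes named above for 8 h was called, and 3 without control replicate 3, when c91374_g1 was not (adjusted p = 0.0948). With the replicate number as a block, c91374_g1 had an adjusted p of 0.0528. After quantile normalization it was 12 higher and 7 lower at 8 h and 0 at 4 h. Voom called 0 at both, limma without the trend 12 and a pseudocount of 0.1 gave 11 at 8 h, and models of the 6 compared libraries gave 0 at 4 h, 0 at 8 h and 1 at 12 h.

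The size of the moderate response differed among 4, 8, 12 and 24 h for 15 genes, with 468 at an unadjusted p under 0.05. Between neighbouring times the added tests called 4 genes for 8 h against 4 h, 0 for 12 h against 8 h (93 at an unadjusted p under 0.05) and 1 for 24 h against 12 h. For c88960_g1 the response grew by 2.28 on the log2 scale (SE 0.58, adjusted p = 0.142) from 12 to 24 h, which did not pass the test. The count of 15 was 201 without control 4 h replicate 2, 40 without moderate 12 h replicate 2, 34 without moderate 4 h replicate 1 and 23 without control 4 h replicate 1; it was 6 without control 24 h replicate 3 and 7, 8 and 5 without moderate 24 h replicates 1, 2 and 3. Quantile normalization gave 26, and a model of the compared groups alone 5.

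Severe and moderate hypoxia differed from each other in 851 genes that were higher and 523 that were lower in severe hypoxia over the mean of 4 to 24 h. The gene c84833_g1 was higher by 5.80 on the log2 scale (SE 0.45, adjusted p = 2.08e-12) and c78926_g1 by 3.84 (SE 0.41, adjusted p = 3.03e-09). In moderate hypoxia, c78926_g1 stood at 2.66 ± 0.574 RPKM at 24 h, against 117 ± 139 at 8 h and 45.9 ± 49.6 at 24 h of severe hypoxia (n = 3). Lower in severe hypoxia were c84317_g3 (-1.96, SE 0.57, adjusted p = 0.0052) and c88827_g1 (-1.74, SE 0.52, adjusted p = 0.00642). At 24 h c88827_g1 stood at 51.1 ± 51.5 RPKM in moderate hypoxia, 2.33 ± 1.78 in severe hypoxia and 16.8 ± 2.70 in control (n = 3), and without 24 h neither fall was called (-1.56 and -1.08). Scaling decided which direction was more frequent: after quantile normalization 640 genes were higher and 759 lower. The mean without 12 h gave 744 calls, and a 2-fold minimum 256.

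By time, severe against moderate hypoxia gave 1 called gene at 0 h, 91 higher and 17 lower genes at 4 h, 247 and 116 at 8 h, 685 and 385 at 12 h, and 398 and 83 at 24 h. The gene called at 0 h was c78658_g1, named after its values were seen, at 108 ± 23.8 RPKM in severe hypoxia, 15.5 ± 7.87 in moderate hypoxia and 40.5 ± 11 in control (n = 3). Its difference was 2.85 on the log2 scale (SE 0.43, adjusted p = 0.000291); against control it was 1.41 in severe hypoxia (adjusted p = 0.439) and -1.45 in moderate hypoxia (adjusted p = 0.64), neither of which passed. In severe hypoxia it rose further to 618 ± 34.9 RPKM at 8 h, where control stood at 50.0 ± 22.4. At 0 h there were 9 calls without moderate 0 h replicate 2, 3 without severe replicate 1, 4 without severe replicate 2, and 0 in a model of the compared groups. At 4 h there were 43 and 51 calls without moderate replicates 2 and 3, 70 and 63 without severe replicates 1 and 3, 65 with voom and 15 in a model of the compared groups. At 8 h there were 226 without moderate replicate 2, 237 without severe replicate 2 and 161 in a model of the compared groups. At 12 h there were 684 without moderate replicate 2, 684 with a 2-fold minimum and 572 in a model of the compared groups. At 24 h there were 312 without moderate replicate 1 and 306 with a 2-fold minimum. Quantile normalization gave 234 higher and 187 lower genes at 8 h, 482 and 486 at 12 h, and 180 and 141 at 24 h.

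Fold changes at the 2 hypoxia levels mostly had the same sign. At 24 h of moderate hypoxia, the fold changes of 2656 genes correlated across genes with those of severe hypoxia at 4, 8, 12 and 24 h with r of 0.407, 0.644, 0.777 and 0.826 (genes are not independent replicates). The first 3 of these use separate control libraries. Of the 442 genes higher in moderate hypoxia at 24 h, 343 were also higher in severe hypoxia at 12 h, where independent lists would share 162.6, and of the 411 lower genes 326 were also lower, where independent lists would share 137.6. The comparison at 24 h shares its 3 control libraries: unchanged simulated groups gave r = 0.502 against the observed 0.826, and the covariance was 0.895 against 0.0728, a difference of 0.822. With 1 of these control libraries used for severe and the other 2 for moderate hypoxia, r was 0.729 on average over the 3 choices (0.654 to 0.785). For the mean of 4 to 24 h, r was 0.813 against a simulated 0.499, and 89.5% of genes had the same sign against a simulated 66.7%. The covariance was 0.351 against 0.018, a difference of 0.333. Both simulations drew each gene independently, so they leave out shifts that 1 control library shares over many genes. With the 12 control libraries divided between the levels, r was 0.598 to 0.742 and the covariance 0.323.

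The severe-response score placed the libraries in order of oxygen level from 8 h on. In severe hypoxia it was 0.80 ± 0.16 (SD, n = 3) at 4 h, 1.67 ± 0.30 at 8 h, 2.41 ± 0.20 at 12 h and 2.13 ± 0.10 at 24 h. In moderate hypoxia it was 0.17 ± 0.51 at 4 h, 0.71 ± 0.31 at 8 h, 0.72 ± 0.46 at 12 h and 1.35 ± 0.07 at 24 h. The genes scored differed between times, for example 1233 higher and 1083 lower genes at 4 h and 1030 and 921 at 24 h. Sizes at different times are therefore not on 1 scale. At 8, 12 and 24 h each severe library lay above each moderate one and each moderate library above each control (exact permutation p = 0.1 for each pair of groups, the smallest that 3 against 3 can give). At 4 h the moderate libraries did not separate from control (exact p = 0.6), and the 3 control libraries spread over an SD of 0.47. Control 4 h replicate 3 had a score of 0.53 and moderate 4 h replicate 2 of -0.29, and moderate 12 h replicate 2 stood at 0.19 against 0.94 and 1.02 for the other moderate 12 h libraries.

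**Figure D3:**
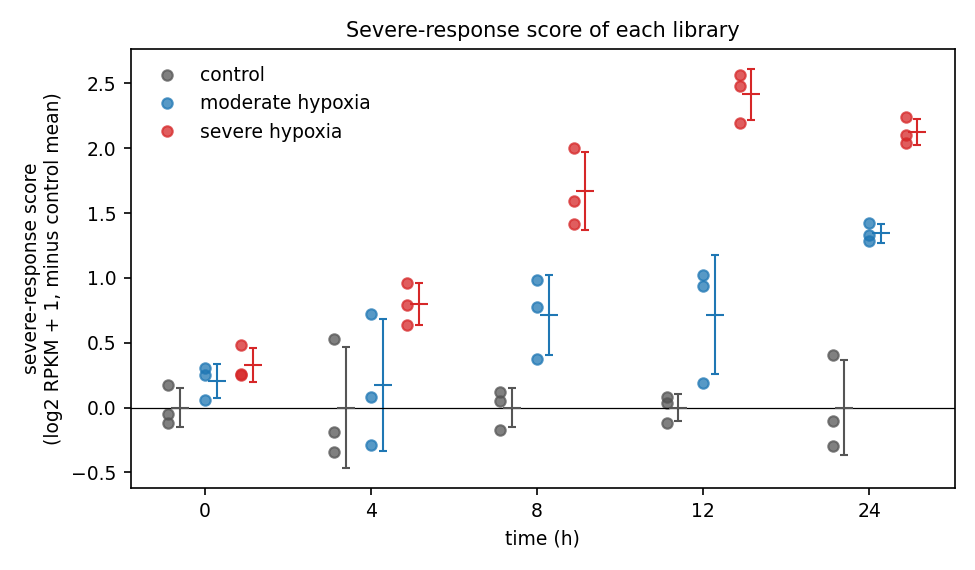
Severe-response score of each library against time in hours (categories, not to scale), in log2 units relative to the control mean of the same time, with 1 point per library and the mean ± SD of 3 libraries beside it. The genes scored differ between times, so sizes compare within a time only. Severe libraries lay at 2.04 to 2.24 and moderate ones at 1.28 to 1.43 at 24 h.

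Among the 5 control times limma called 2 genes, named after their values were seen: c83084_g11, with 2.31 ± 0.13 RPKM at 0 h, 1.05 ± 0.112 at 4 h and 4.77 ± 2.49 at 12 h, and c90605_g2, with 0.381 ± 0.43 at 4 h and 2.96 ± 1.34 at 24 h (n = 3, adjusted p = 0.029 for both). With these included, 269 genes had an unadjusted p under 0.05. In simulated libraries this test recovered 12% of genes changed 2-fold and 74% of those changed 4-fold at 24 h alone, so few calls do not show that the control group stayed the same over the 24 h of fasting. The count was 0 without control 0 h replicate 3, 4 h replicate 3, 8 h replicate 1 or 2, 12 h replicate 1 or 2, or 24 h replicate 1 or 3, and 49 without control 4 h replicate 2. The call of c83084_g11 also ended without control 4 h replicate 1 or 8 h replicate 3. The count was also 0 with the replicate number as a block, with quantile normalization, with voom and in a model of the control group alone, and 1 with a pseudocount of 0.1, when c90605_g2 was not called, or with a 2-fold minimum.

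**Figure D4:**
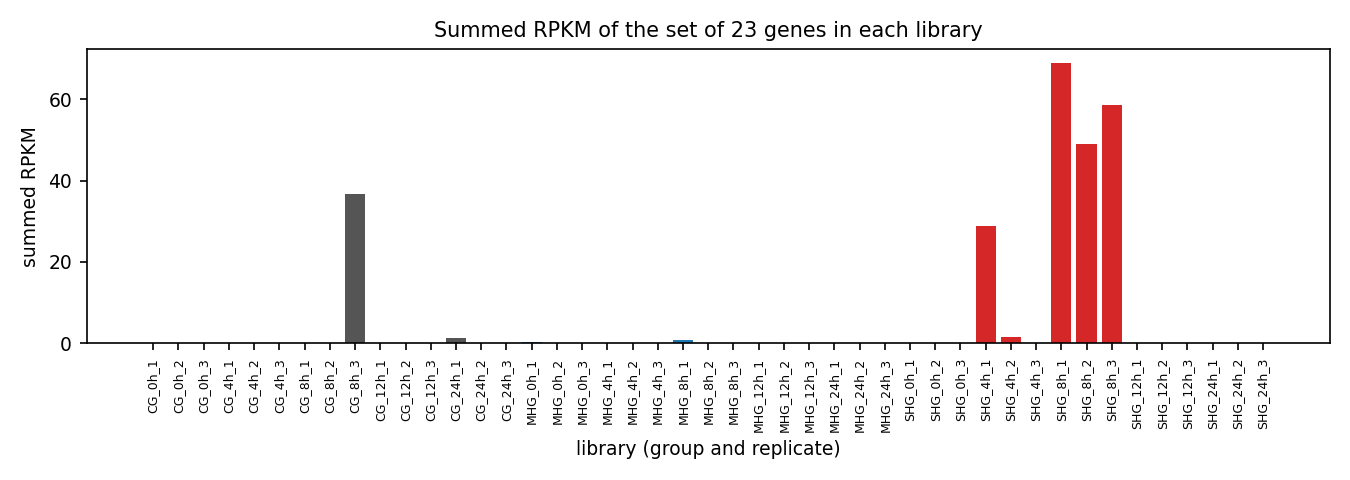
Summed RPKM of the 23 genes with reads in all 3 severe 8 h libraries and in at most 4 of the 39 libraries outside control 8 h and severe 8 h, in each of the 45 libraries (CG control, MHG moderate hypoxia, SHG severe hypoxia, with time and replicate). The bars stand at 36.6 in control 8 h replicate 3, 28.8 in severe 4 h replicate 1 and 49.1 to 68.9 in the severe 8 h libraries.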

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

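The tests on the set of 23 genes, the test of exchanged labels at 12 h and the comparisons of library totals were chosen only after the result was seen; the regroupings of libraries and the test of exchanged labels at 4 h were set before it. The response to severe hypoxia differed between sampling times for 644 genes, by a test of the difference itself, and the response to moderate hypoxia for 15. Of 100 regroupings of the libraries across the times of their own oxygen level, 1 gave as many as 644 genes, the real one. The highest other gave 113. The rule by which genes were listed is not known. If it used differences between these same groups, the real grouping was favoured in advance, so chance is not excluded by this. For moderate hypoxia 4 of 100 gave at least 15, a share under 0.05. The highest other gave 196, the same limit of the list applies, and the regrouping was 1 of many, so chance is not excluded. A regrouping that calls several times the real count points to a structure of the samples that the times do not set.

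The mean contrasts were set against 100 regroupings within each time. For severe hypoxia only the real grouping reached 2287 (1 of 100, highest other 1583). For moderate hypoxia only the real one reached 990 (1 of 100, highest other 705). For severe against moderate hypoxia only the real one reached 1374 (1 of 100, highest other 837). The real counts exceeded all regroupings within the listed genes, but the unknown listing rule may have favoured them, so chance is not excluded. For the control group over time, 21 of 100 gave as many as the 2 real calls, with up to 78, so chance cannot be excluded. The single times have 10 splits of 6 libraries, too few for a share under 0.05. In severe hypoxia against control the real split and the highest other gave 254 and 28 at 4 h, 1065 and 15 at 8 h, 1866 and 0 at 12 h, and 1771 and 0 at 24 h, so 1 of 10 splits gave as many at each of these times. At 0 h the real count was 0, so all 10 did, and the highest other was 0. In moderate hypoxia the real split and the highest other gave 6 and 1 at 8 h and 853 and 0 at 24 h, with 1 of 10 as large, and 0 and 2 at 0 h and 0 and 0 at 12 h, with 10 of 10. Severe against moderate hypoxia gave 1 and 2 at 0 h, with 4 of 10 as large, and 108 and 3 at 4 h, 363 and 12 at 8 h, 1070 and 0 at 12 h, and 481 and 1 at 24 h, with 1 of 10.

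At 4 h of moderate hypoxia the real split called 1 gene, 4 of 10 splits called as many, and the split of control replicates 1 and 3 with moderate replicate 1 against the others called 367. That count points to a structure of the samples other than the oxygen level. By score, control 4 h replicate 3 lay near the hypoxia libraries (0.53) and moderate 4 h replicate 2 near the controls (-0.29). Exchanged labels could give this: the distance of control 4 h replicate 3 to the other moderate libraries was 0.896 of that to its own group, just under the bound of 0.9 set for an exchange, but the partner needed for it was at 0.934, the library nearest to the first was control 0 h replicate 1, and a split with both exchanged called 0 genes, so this stays open. Control 4 h replicate 3 was far from both groups, at 1.081 and 1.206, against a median distance of 0.654 within the 15 groups. The leading falls of severe hypoxia, c84317_g3 and c84881_g1, stood at 138 and 142 RPKM in it. In the moderate 4 h libraries they stood at 6.31 to 11.6 and 4.95 to 9.05 RPKM, so its score did not extend to these genes. A lower total depth is argued against by the 30891302 reads of control 4 h replicate 3, within the range of the other 44 libraries, but it had the lowest share of its reads in listed genes of all 45 libraries (10.9%) and the most listed genes without reads (122), so a difference in the makeup or quality of its RNA stays open and, like a difference between the fish sampled, was not tested.

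A set of 23 genes, picked for reads in the 3 severe 8 h libraries and in at most 4 of the 39 libraries outside control 8 h and severe 8 h, had reads in control 8 h replicate 3, none in control 8 h replicates 1 and 2, and at most 47 reads in each of 40 other libraries; severe 4 h replicate 1 held 14 of the genes. The tables argue against a wrong label, since control 8 h replicate 3 had a score of 0.05, and against carry-over of severe 8 h RNA, since 47 other genes high in severe 8 h stood in it at a median share of 0.001 (90th percentile 0.048) of the severe level, against 0.632 for the set. They also argue against a liver response to severe hypoxia as the whole cause, since the set, picked without use of the control 8 h libraries, summed to 36.6 RPKM in this control library. A second source of RNA in these livers could give such a set; its genes kept their ranks only in part (rank correlation 0.58 between this library and the severe 8 h mean), so this stays open, and the genes have no names by which a source could be tested.

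Moderate 12 h replicate 2 had a score of 0.19, against 0.94 and 1.02 for the other moderate 12 h libraries, and without it 300 genes were called where 0 were with it. An exchange with a control 12 h library is argued against, since the highest control score at 12 h was 0.082. Lower depth is argued against by its total of 31864005 reads, within the range of the other libraries. A wrong label without a partner, an exchange with a library of another time and fish that responded less were not tested and remain open.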

How the results depend on the processing

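The limma fit with voom weights and the mean contrasts without 3 libraries were chosen only after the result was seen; the others were planned before the data were examined. Of 448 values of counts and correlations under alternatives, 368 stayed near the reported value and 80 moved. A count stayed when it lay within 1.5 times the reported one. A correlation stayed when it shifted by less than an SD estimated from the fits with 1 library left out. Over 42 gene comparisons picked by the naming rules and 839 alternatives, 721 kept their call and direction, 118 lost the call and 0 changed sign. These genes were picked for their calls in the same data, and the alternatives refit the same or nearly the same libraries. A change of sign was therefore unlikely from the start. For the genes named in the control group over time the change is an absolute value, which cannot change sign. With limma without the trend, moderate hypoxia at 8 h gave 12 calls. Quantile normalization gave 0 for moderate hypoxia at 4 h, 19 at 8 h, 0 for the control group over time and 26 for moderate hypoxia by time. A pseudocount of 0.1 gave 0 for moderate hypoxia at 4 h, 11 at 8 h and 1 for the control group over time. A 2-fold minimum gave 560 for moderate hypoxia at 24 h, 684 for severe against moderate hypoxia at 12 h and 306 at 24 h, 668, 46 and 256 for the means of severe, moderate and severe against moderate hypoxia, and 1 for the control group; fewer genes can pass it by construction. Models of the compared groups alone, which have fewer libraries to estimate the spread, gave 3 for severe hypoxia at 4 h, 0, 0 and 1 for moderate hypoxia at 4, 8 and 12 h, 0, 15, 161 and 572 for severe against moderate hypoxia at 0, 4, 8 and 12 h, 0 for the control group over time, and 321 and 5 for severe and moderate hypoxia by time. The mean without 12 h gave 627 for moderate hypoxia and 744 for severe against moderate hypoxia, and without 24 h 190 for moderate hypoxia. Voom gave 0 for moderate hypoxia at 4 and 8 h, 65 for severe against moderate hypoxia at 4 h and 0 for the control group over time. Dividing the controls between the levels took the correlation of the mean fold changes from 0.813 to a mean of 0.679 and the covariance from 0.351 to 0.323; it also left 4 or 8 instead of 12 control libraries per level, so an effect of sharing and one of fewer libraries were not separated. Without the 3 libraries that stood apart, the means gave 2280, 1306 and 1342 calls. The cause of the other moves was not tested.

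With the replicate number as a block, the control group over time gave 0 calls and no other count moved by over 1.5 times; severe hypoxia at 24 h gave 1786, for example. The numbers were compared only between oxygen levels at the same time: in 0 of 15 comparisons did all 3 same-numbered libraries deviate together with r over 0.1 (r from -0.49 to 0.25), though in severe hypoxia against control at 12 h and moderate hypoxia against control at 0 h each correlated best with its own number.

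Leaving out each library in turn gave, from lowest to highest, 138 to 342 calls for severe hypoxia at 4 h, 0 to 6 for moderate hypoxia at 0 h, 0 to 66 at 4 h, 0 to 11 at 8 h, 0 to 300 at 12 h and 426 to 880 at 24 h, 1 to 9 for severe against moderate hypoxia at 0 h, 43 to 158 at 4 h, 226 to 381 at 8 h, 684 to 990 at 12 h and 312 to 384 at 24 h, 0 to 49 for the control group over time, 423 to 856 for severe hypoxia by time and 5 to 201 for moderate hypoxia by time. The libraries behind the moves over 1.5 times are named beside the counts they move. The mean contrasts and severe hypoxia at 8, 12 and 24 h stayed within 1.5 times. The tests of fixed gene lists were not run, since the genes have no names. Small changes were hard to detect with these libraries: simulated 2-fold changes were recovered for 68% of genes in the mean contrast of severe hypoxia and 26% at 4 h.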

Other observations

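The tests of the 0 h score and of a delayed course were chosen only after the result was seen; the tests of genes that follow c84833_g1 and c84317_g3 were set before theirs. Libraries of 1 group differed widely in a few genes. In severe hypoxia c84833_g1 ranged from 14.9 to 723 RPKM at 8 h and from 16.7 to 307 RPKM at 24 h, and c78926_g1 from 9.34 to 274 RPKM at 8 h. In control, c84317_g3 stood at 74.8, 1.21 and 35.8 RPKM and c84881_g1 at 65.1, 0.819 and 25.9 RPKM in replicates 1, 2 and 3 at 8 h, and c88827_g1 at 90.2, 1.99 and 50.9 RPKM.

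Such spread may reflect a state of the fish sampled that moves several genes together. For c84317_g3 in the 15 control libraries, 15 genes followed it at r above 0.9 in deviations from the group means, more than the 12 of the highest of 100 permutations within time (median 0), a narrow margin. Among these genes was c84881_g1, at r = 1 after rounding. For c84833_g1 in the 12 severe libraries at 4 to 24 h, 5 genes followed it, fewer than the 11 of the highest permutation (median 1), so no wider set was shown, although c78926_g1 followed it at r = 0.98. What such a state is was not tested.

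At 0 h the mean score was 0.33 ± 0.13 in severe and 0.20 ± 0.13 in moderate hypoxia, relative to a control mean of 0 with an SD of 0.15 (n = 3). Neither group can pass alone with 3 libraries (exact permutation p = 0.1 for severe and 0.2 for moderate hypoxia), and moderate 0 h replicate 2, at 0.058, lay within the control range of -0.119 to 0.171. A hypothesis is that the response began while the oxygen was being lowered. With both groups pooled, 5 of the 6 hypoxia libraries lay above every control, with a difference of 0.267 (2-sided exact permutation p = 0.0238 over 84 splits of 6 against 3). Since each oxygen level had its own tanks and the tank of each library is not known, a response and a difference between tanks cannot be told apart.

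Moderate hypoxia at 24 h could be the severe course running later. With other control libraries in each fold change, the moderate 24 h changes correlated across genes with those of severe hypoxia at r of 0.328 at 4 h, 0.601 at 8 h, 0.743 at 12 h and 0.729 at 24 h, so 12 h exceeded 24 h by 0.014. The choice of control libraries alone moved the value at 12 h from 0.713 to 0.775 and that at 24 h from 0.654 to 0.785, so an earlier and an equal stage cannot be told apart.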
